A study of Mus musculus with 18 samples.

How the data were processed

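Gene expression was measured by RNA sequencing in the neocortex of 6 CD-1 mice, an outbred stock in which animals differ from one another in sequence. Per the labels, plasmids were brought into the embryonic cortex by in utero electroporation on embryonic day 14.5. This method injects DNA into the fluid space of the embryonic brain and drives it by electric pulses into the cells lining that space. At postnatal day 7 the brains were cut into 300 µm sagittal sections, and layers 2-3 (L2-3), layer 4 (L4) and layers 5-6 (L5-6) were dissected and pooled for each mouse. The labels state total RNA and Illumina TruSeq libraries. They describe the L4 cells as GFP-positive and the cells of L2-3 and of L5-6 as GFP-negative. They call both L2-3 and L5-6 infragranular, although L2-3 lies above the granular layer.

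The authors deposited a table of raw read counts for 54446 genes in 18 libraries, with no normalization. The values were whole numbers. Per the submitters' processing notes, STAR and HTSeq were used with the mm10 genome. Their versions, the gene models, the handling of reads that match several places and the use of strand are not given in the sources used here. Most identifiers match the GENCODE M21 mouse annotation: 53229 of 54446 matched with their version and 54409 without it. That annotation was used for gene positions and gene types only. Reads of genes with near-identical copies, such as processed pseudogenes, and reads of overlapping or antisense genes are uncertain, because the counting could have split them.

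Groups were taken from the sample titles. There were 3 GFP mice, 2 mice with human FOXP2 (huFOXP2) and 1 mouse with mouse Foxp2 (moFoxp2), each with 1 library per layer. The huFOXP2 and moFoxp2 mice together are called FOXP2 mice. Each mouse was counted as 1 replicate. Library totals ranged from 10111149 counts (GFP mouse 1, L4) to 23404528 counts (huFOXP2 mouse 1, L2-3). No 2 libraries of a group were identical. A chi-square per degree of freedom between replicate libraries, over genes with at least 10 reads in the pair, lay between 8.89 and 54.3 over 12 pairs, so no library was counted as a copy of another. The 6 pairs with GFP mouse 1 had 23.5 to 54.3 and the 6 others 8.89 to 12.4. The sex read from Xist and Y-linked genes was the same in all 3 libraries of each mouse. It was female in 1 GFP mouse and 1 FOXP2 mouse.

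Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after TMM normalization and the filterByExpr filter (minimum count 10, minimum total count 15). Adjusted p-values are from the Benjamini-Hochberg method over the genes tested in a comparison, with a threshold of 0.05. Standard errors of log2 fold changes were obtained as the fold change divided by the square root of the F statistic. Levels are given as CPM, counts relative to the library total scaled by its TMM factor, as mean ± SD over mice. FOXP2 and GFP mice were compared within each layer and over the summed counts of each mouse. The difference of the FOXP2 effect between layers was tested with the mouse as a block. Contrasts between layers in GFP mice also had the mouse as a block. huFOXP2, moFoxp2 and GFP mice were compared within each layer in 1 fit over all 18 libraries. There the lone moFoxp2 library of a layer was assumed to vary like those of the other groups, and the layers of a mouse were taken as independent, although they are correlated.

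The labels state that each layer was pooled per mouse, so libraries of 1 group with the same replicate number were taken as 1 mouse. This was checked on deviations from the means of FOXP2 or GFP libraries of a layer, over 14330 genes. Libraries of the same mouse correlated at 0.268 to 0.698 (median 0.501), above 0.1 in 18 of 18 pairs. GFP and FOXP2 mice shared only a replicate number.

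Gene lists were fixed before the data were examined, as were the comparisons, the other settings to try and the rule for named genes. The 30 lists covered neurons of each cortical layer, interneurons, non-neuronal cells, neighbouring brain regions, receptors, channels and adhesion molecules, reported FOXP2 targets and partners, and signs of activity, stress and RNA content. They held 331 different genes. A list was tested against all other genes with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated correlation, and by itself with fry for a shift in 1 direction. With an estimated correlation 0 lists passed in any comparison, those between layers of GFP mice included. A list that failed it is thus not shown to be unchanged. The rule for named genes took Foxp2 and Cntnap2 always. It then took up to 10 genes per direction with the largest fold among those past the threshold (5 for differences between layers and between species), whose groups did not overlap (or, with a mouse block, whose sign was the same in every mouse) and whose mean was at least 1 CPM. Where fewer than 3 passed in a direction, the 5 genes of smallest p were named as values. Of each list that passed or held a called gene, the 2 members of smallest p were named. Sex-linked check genes and predicted genes with Gm or Rik names were left out of the rule, so any Gm gene in the text was chosen after its values were seen.

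The procedure was tested on simulated data, drawn for the real genes from their means, spread and library sizes, with 200 genes changed by known folds. Of genes changed 2-fold and 4-fold, it recovered 70% and 91% in the FOXP2 comparison in L4 (14589 genes), 72% and 91% in L2-3 (15270 genes) and 66% and 92% in L5-6 (15381 genes). For the difference between the effects in L5-6 and L2-3 it recovered 57% and 85% (15937 genes), and for huFOXP2 against moFoxp2 in L2-3 16% and 67% (16785 genes). Unchanged genes called in these 5 runs numbered 9, 9, 12, 0 and 5 in this order. Simulated genes vary independently, unlike real ones, and the mice of a layer were drawn from 1 mean. With 200 genes changed at once the adjusted threshold is easier to reach than with few changed genes. The recovered shares can therefore overstate what the real comparisons find. Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, leaving out each mouse in turn, sex as a term, other sets of libraries, and fits with or without blocks. A score of meningeal genes as a term was added after seeing the data. Raw reads, exon-level counts and the sequences of the plasmids were not used here. Results of some single genes are not reported here.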

Results

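RNA levels were measured in 18 libraries from 6 mice at postnatal day 7, with 1 library of L2-3, 1 of L4 and 1 of L5-6 from each mouse. The GFP group held 3 mice, the huFOXP2 group 2 and the moFoxp2 group 1. Total counts per library ranged from 10111149 (GFP mouse 1, L4) to 23404528 (huFOXP2 mouse 1, L2-3). Over 1000 genes of high variance, the first 3 principal components held 53.2%, 17.9% and 6.05% of the variance. The series compares neocortex electroporated with GFP alone with neocortex that also received human or mouse FOXP2, and FOXP2 and GFP mice were therefore compared in each layer.

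Foxp2 encodes a forkhead transcription factor found in the cortex mainly in deep-layer neurons. The gene (ENSMUSG00000029563.16) lies on mm10 chromosome 6 from 14901349 to 15441977. In L4, Foxp2 rose by 2.75 ± 0.30 (log2 fold change ± SE, edgeR adjusted p = 0.0247), from 6.63 ± 1.72 CPM in GFP mice to 44.2 ± 17.9 CPM in FOXP2 mice (SD, n = 3 each). In L2-3 it stood at 31.03 ± 17.7 CPM in FOXP2 mice and 4.54 ± 2.50 CPM in GFP mice, a difference of 2.78 ± 0.51 that did not pass (adjusted p = 0.0829). In L5-6, where GFP mice already had 61.0 ± 7.98 CPM, FOXP2 mice had 62.4 ± 20.1 CPM (0.02 ± 0.23, adjusted p = 0.976). Cntnap2 (ENSMUSG00000039419.17, chromosome 6, 45059357 to 47304213) encodes a neurexin-family adhesion protein and is a reported FOXP2 target. It did not pass in any layer, with differences of 0.27 ± 0.15 in L4 (166 ± 4.41 against 137 ± 30.9 CPM), -0.01 ± 0.13 in L2-3 and 0.42 ± 0.15 in L5-6 (134 ± 9.98 against 99.3 ± 19.9 CPM), and adjusted p of 0.9999, 0.987 and 0.713. The L4 call of Foxp2 was lost without GFP mouse 1 (adjusted p = 0.0533), GFP mouse 3 (0.1003) or the moFoxp2 mouse (0.0601), with sex as a term (0.1004) and over numbers 1 and 2 without a block (0.0756), within a range of 4.59e-57 to 0.1004 over 14 alternatives. In the fits that lost this call the difference was 2.59 to 2.90. Reads of the introduced cDNA and of the endogenous gene were not separated, and the annotated span of Cntnap2 overlaps 28 other genes.

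**Figure D1:**
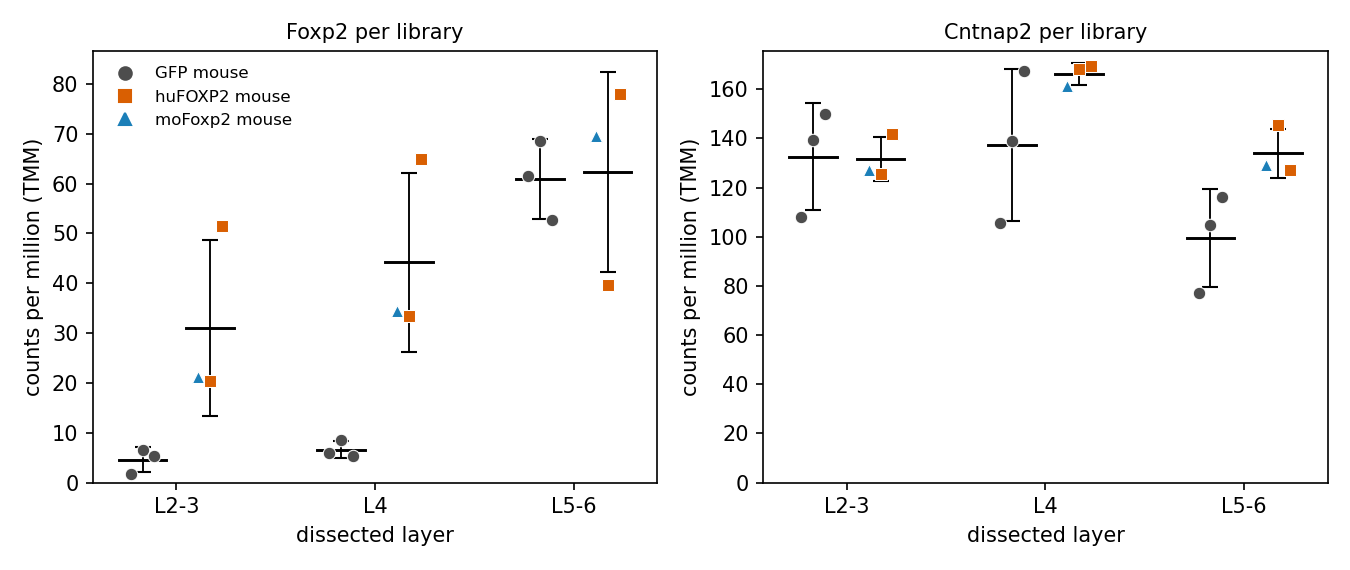
Foxp2 and Cntnap2 levels in CPM in each library, by layer and group, with the mean and SD of FOXP2 and GFP mice (n = 3 each). Foxp2 had means of 44.2 and 6.63 CPM in L4 of FOXP2 and GFP mice, and 62.4 and 61.0 CPM in L5-6.

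Processed pseudogenes, copies of messenger RNAs inserted back into the genome, passed in all 3 layers with the largest folds. Gm6166 (ENSMUSG00000074280.6, chromosome 9, 57483963 to 57484371) was higher in FOXP2 mice by 7.49 ± 0.26 in L4, 6.62 ± 0.28 in L2-3 and 7.81 ± 0.32 in L5-6 (adjusted p = 3.66e-06, 8.87e-05 and 0.000114). Its level in L4 was 54.7 ± 2.99 CPM against 0.341 ± 0.181 CPM. Gm11942 (ENSMUSG00000094344.1, chromosome 4, 32964888 to 32965232) was higher by 6.99 ± 0.53, 6.55 ± 0.52 and 6.13 ± 0.48 (adjusted p = 0.00142, 0.00478 and 0.00681). Rpsa-ps10 (ENSMUSG00000047676.6, chromosome 3, 150072658 to 150073542), a copy of the ribosomal protein gene Rpsa, differed by -5.74 ± 0.36, -5.63 ± 0.32 and -6.15 ± 0.34 (adjusted p = 0.000398, 0.00054 and 0.000645), with 3.69 ± 0.705 against 198 ± 84.4 CPM in L4. The call of Gm11942 was lost in L5-6 without GFP mouse 2 (adjusted p = 0.0533) and over numbers 1 and 2 without a block (0.0801, range over alternatives 1.54e-31 to 0.0801), and in L2-3 with the meningeal score as a term (0.0543, range 1.13e-38 to 0.0543). Gm6166 and Gm11942 were outside the rule for named genes and were chosen after their values were seen. Reads of such near-identical copies are uncertain.

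**Figure D2:**
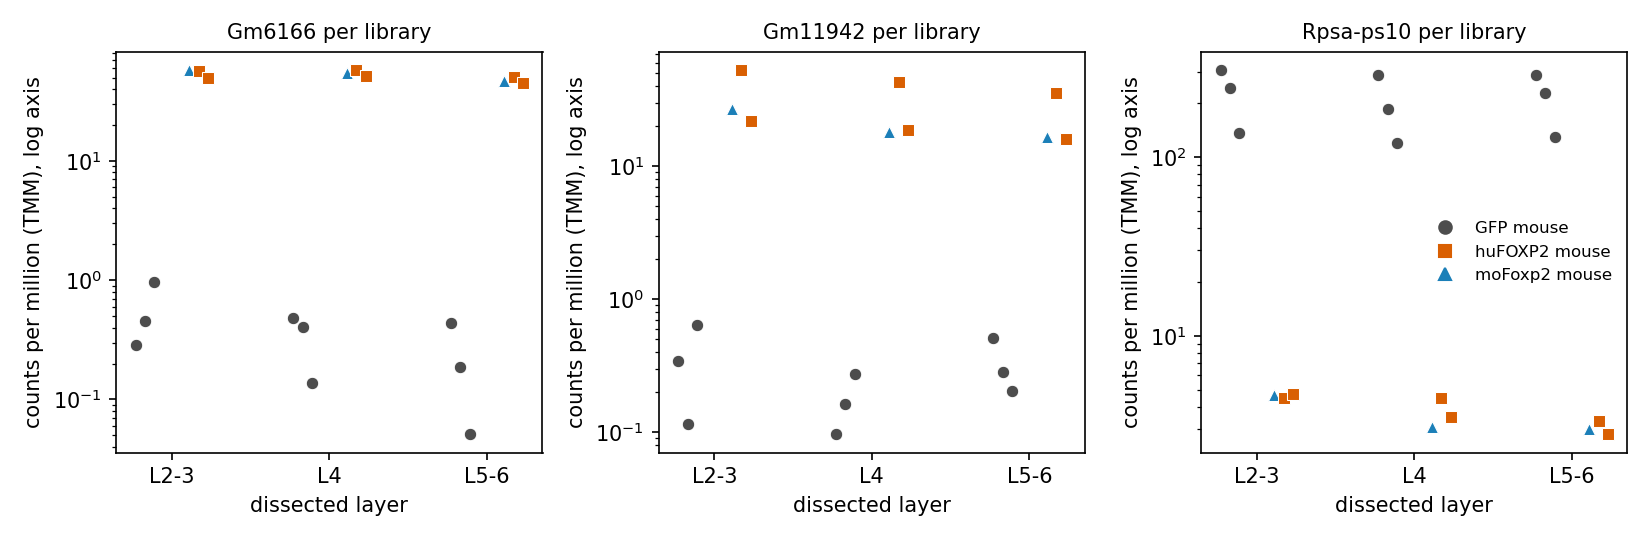
Levels of Gm6166, Gm11942 and Rpsa-ps10 in CPM on a log axis in each of the 18 libraries, by mouse group and layer. In L4, Gm6166 had means of 54.7 CPM in FOXP2 mice and 0.341 CPM in GFP mice.

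In L4, the layer whose cells the labels call GFP-positive, Foxp2 and these pseudogenes were the 4 of 14544 genes that passed (3 higher, 1 lower). Their groups did not overlap, which chance gives for 10% of genes. No member of the gene lists passed over all genes. With fry 0 lists passed. Of 13 markers of layer 6 and subplate neurons, 10 were below 0, and 3 fell when adjusted over the list alone (median -0.52, -0.27 without GFP mouse 1, camera adjusted p = 4.46e-08, adjusted p = 0.167 with an estimated correlation). These were Nxph3 (-2.08 ± 0.34), Syt6 (-1.16 ± 0.22) and Rprm (-0.89). Of 13 interneuron markers, 12 were above 0 and 4 rose when adjusted over the list alone (median 0.35, adjusted p = 4.46e-08, adjusted p = 0.62 with an estimated correlation). They were Vip, Dlx1, Adarb2 and Gad1, and Vip, a neuropeptide of one interneuron class, had 32.5 ± 2.70 against 22.4 ± 2.48 CPM. Layer 5 markers had a median of -0.24, with Parm1 higher and Fezf2 (-1.05) and Crym (-1.43 ± 0.39) lower when adjusted over the list alone (adjusted p = 0.0298, adjusted p = 0.959 with an estimated correlation). Nxph3, Rprm and Fezf2 were also higher in L4 than in L2-3 of GFP mice, as given below. Different tissue content of the L4 dissections was not separated from an effect of FOXP2 on these deep-layer markers. Medians of layer 2-3 markers (0.12), GABA-A receptor genes (0.11, -0.03 without GFP mouse 1), hippocampal markers (0.33) and heat shock genes (0.16) also passed at the preset correlation, with adjusted p = 0.742, 0.959, 0.742 and 0.742 with an estimated correlation. The 8 measured reported FOXP2 targets had a median of 0.17 and did not pass (adjusted p = 0.189). An unadjusted p under 0.05 was found for 457 genes, fewer than the 727 that chance gives, and DESeq2 called 32.

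In L2-3, smooth muscle actin Acta2 rose by 1.11 ± 0.12 (47.1 ± 5.45 CPM in FOXP2 mice against 21.9 ± 0.521 CPM in GFP mice, n = 3 each, adjusted p = 0.0331). The phospholipid transfer protein gene Pltp (0.96 ± 0.11) and Egfl8 (1.56 ± 0.20) also rose. Lower were the lipoprotein lipase gene Lpl (-0.81 ± 0.10, 140 ± 9.70 against 246 ± 22.7 CPM), Plcxd2 (-0.79 ± 0.09), Dixdc1 (-0.81 ± 0.10), the microRNA gene Mir6236 (-1.32 ± 0.16) and the AMPA receptor auxiliary subunit gene Shisa6 (-0.78 ± 0.10), each at adjusted p = 0.0494, as were Pltp and Egfl8. In all, 11 of 15241 genes passed, 5 higher and 6 lower, with the pseudogenes among them and no overlap between groups (10% of genes by chance). The split was 3 higher and 1 lower with RLE size factors, and DESeq2 called 755 genes. An unadjusted p under 0.05 was found for 2412 genes, 1518 higher and 894 lower, more than the 762 that chance gives. Genes vary together, and this excess itself was not tested. Without GFP mouse 1 there were 195 calls, and without any one of the other mice 3 to 5. The call of Acta2 was lost without GFP mouse 2 (adjusted p = 0.0729), GFP mouse 3 (0.123), the moFoxp2 mouse (0.150), huFOXP2 mouse 1 (0.246) or huFOXP2 mouse 2 (0.0664), with sex as a term (0.0764), over numbers 1 and 2 with a block (0.190) or without (0.274) and in a fit over 18 libraries (0.295), within a range of 4.13e-11 to 0.295 over its alternatives. Pltp, Egfl8, Lpl, Plcxd2, Dixdc1, Mir6236 and Shisa6 were lost without each of the same mice, with sex as a term, with RLE size factors and over numbers 1 and 2 without a block. With the block all but Mir6236 were lost, and in the fit over 18 libraries Egfl8, Lpl, Plcxd2 and Shisa6. With the meningeal score of the library as a term, chosen after seeing the data, 2 of the 11 calls were kept, and Acta2 and these 7 genes were lost. Their folds changed little there, from 1.11 to 1.21 for Acta2, from 1.56 to 1.61 for Egfl8 and at most from -0.78 to -0.63 for Shisa6, so the lost calls do not show that meningeal content carries these differences.

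No member of the gene lists passed over all genes in L2-3, while 16 lists passed as a whole with camera at the preset correlation, 0 at an estimated correlation and 0 with fry. Markers of non-neuronal cells were mostly above 0. GFP mouse 1 stood apart here too, with a meningeal score of 5.27 (mean log2 CPM) against 6.74 and 6.43 in the other GFP mice and 6.86 to 7.58 in FOXP2 mice. Of 9 meningeal fibroblast markers, 9 were above 0 and 8 rose when adjusted over the list alone (median 0.99, 0.67 without GFP mouse 1, adjusted p = 4.37e-05). All 4 red blood cell markers (median 1.18) and 5 of 6 Cajal-Retzius markers (median 0.92) rose when adjusted over the list alone, as did 6 of 11 microglia markers (median 0.45), 5 of 10 endothelial and pericyte markers (median 0.48) and 5 of 10 astrocyte markers (median 0.55). Without GFP mouse 1 these medians were 1.01, 0.72, 0.77, 0.56 and 0.55 in this order, and that of layer 4 markers, given below, was -0.32. Examples were the hemoglobin gene Hba-a1 (1.39 ± 0.29), the gap junction gene Gjb6 (1.20 ± 0.25) and the glial filament gene Gfap, at 861 against 390 CPM (1.14 ± 0.23, adjusted p = 0.0942 over all genes). Retinoic acid pathway genes (median 0.76, 4 of 13 higher when adjusted over the list alone), interneuron markers (0.45, 3 of 14), ribosomal protein genes (0.21, 0 of 18) and cell cycle genes (0.21, 0 of 9) also passed above 0. Below 0 were layer 4 markers (median -0.54, 1 of 8 lower when adjusted over the list alone), layer 2-3 markers (-0.21, 5 of 11), GABA-A receptors (-0.31, 3 of 12), potassium and HCN channels (-0.27, 7 of 18), glutamate receptors (-0.21, 4 of 19) and contactin and neurexin family genes (-0.34, 1 of 17). Rorb, a layer 4 transcription factor, had 49.3 ± 9.53 against 140 ± 59.8 CPM (-1.51 ± 0.30, adjusted p = 0.0932). With an estimated correlation adjusted p of these lists lay between 0.335 and 0.422. Reported FOXP2 targets had a median of 0.04 (adjusted p = 0.677).

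In L5-6, no gene other than the pseudogenes passed (3 of 15330 genes, 2 higher and 1 lower, no overlap of groups as in 10% of genes by chance). At an unadjusted p under 0.05 there were 946 genes (766.5 by chance), and DESeq2 called 56. Non-neuronal markers lay on the low side. All 12 oligodendrocyte lineage markers were below 0 (median -0.72, adjusted p = 5.77e-05, 0 past the threshold when adjusted over the list alone). All 5 choroid plexus and ependyma markers were below 0 and 3 fell when adjusted over the list alone (median -1.77, adjusted p = 5.29e-05), among them Foxj1, a regulator of motile cilia, at 3.46 ± 0.963 against 17.1 ± 8.87 CPM (-2.30 ± 0.39, adjusted p = 0.422 over all genes). All 13 layer 6 and subplate markers and all 9 cell cycle genes were below 0 as well (medians -0.20 and -0.63). Lower medians that passed were also those of astrocyte (-0.38), endothelial (-0.21), striatal (-0.75), retinoic acid pathway (-0.49) and ribosomal protein genes (-0.12). Above 0 were layer 2-3 markers (median 0.47), layer 4 markers (0.50), GABA-A receptors (0.24), potassium and HCN channels (0.22) and contactin and neurexin family genes (0.21, 15 of 17 above 0, adjusted p = 0.000691). With an estimated correlation all of these had adjusted p between 0.559 and 0.617, and 0 lists passed with fry. GFP mouse 1 stood apart in L5-6, with an oligodendrocyte score of 7.92 (mean log2 CPM) against 6.40 and 6.98 in the other GFP mice and 6.17 to 6.80 in FOXP2 mice, and 7.50% mitochondrial counts against 4.38% and 4.90%. Without that mouse the medians were -0.23 for oligodendrocyte, -1.06 for ependyma, 0.04 for astrocyte and -0.02 for endothelial markers, and 0.06 for GABA-A receptors, 0.08 for potassium and HCN channels and 0.09 for contactin and neurexin family genes. Adjusted over the list alone, 1 striatal and 1 retinoic acid pathway gene fell (Rgs9 and Crabp1), and no member of any list passed over all genes.

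**Figure D3:**
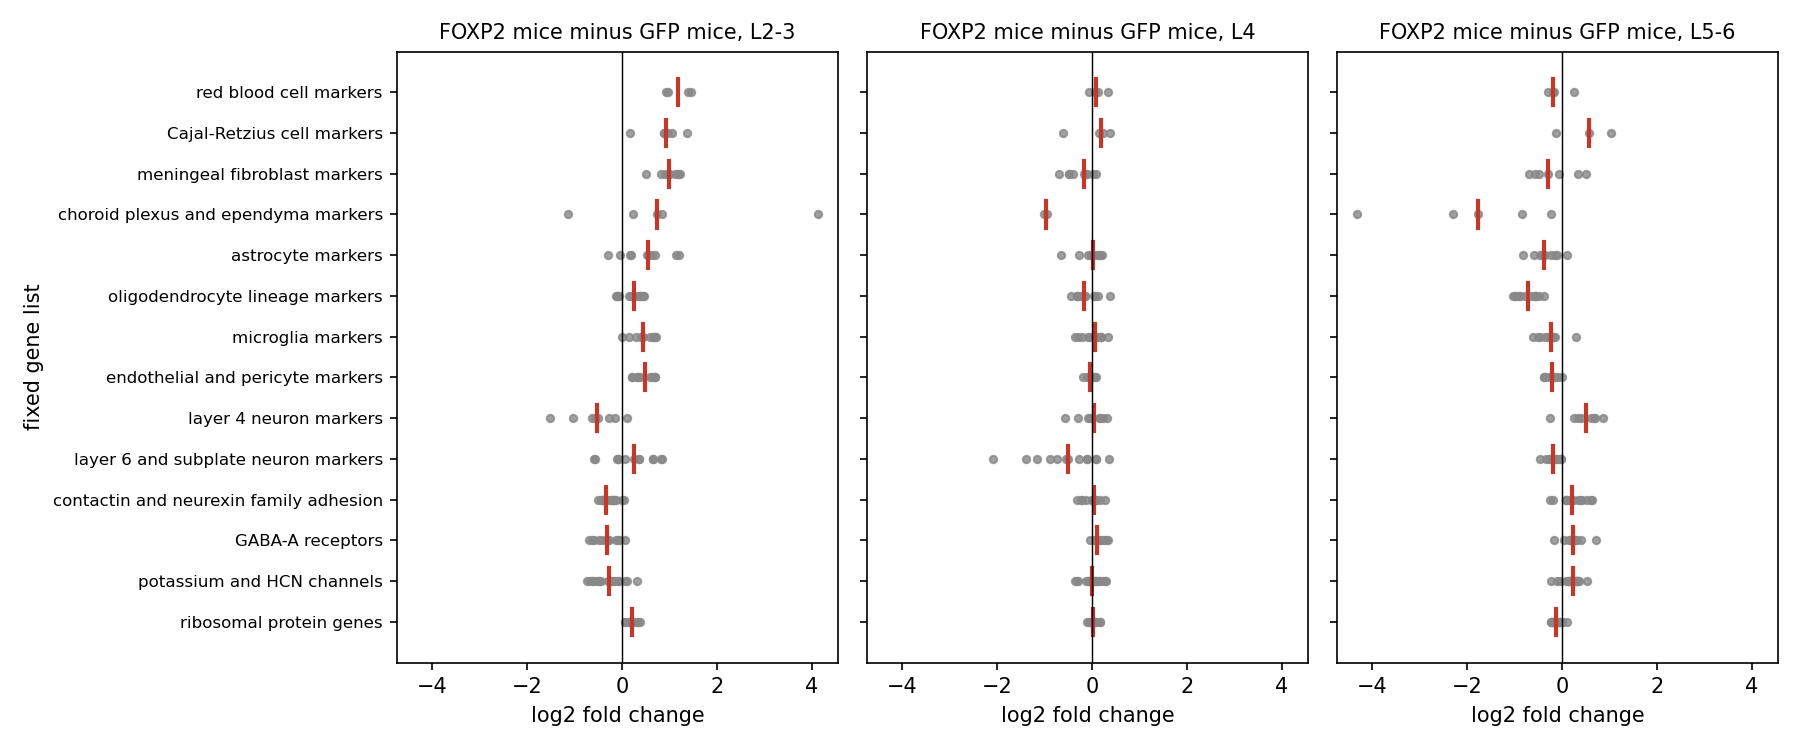
Log2 fold changes of FOXP2 against GFP mice in L2-3, L4 and L5-6 for the members of 14 gene lists (grey points, 1 per gene), with list medians as red bars. Meningeal fibroblast markers had a median of 0.99 in L2-3, layer 6 and subplate markers one of -0.52 in L4, and oligodendrocyte lineage markers one of -0.72 in L5-6.

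**Figure D4:**
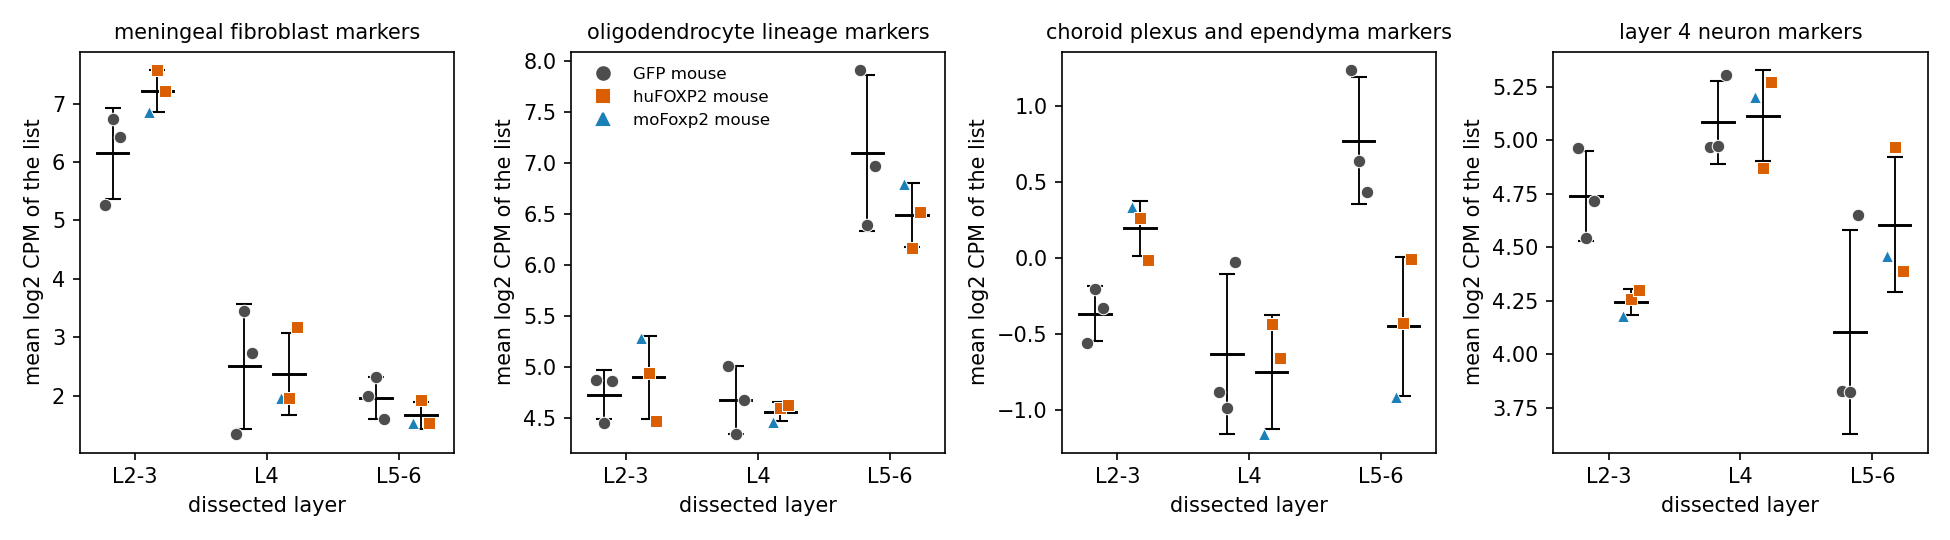
Mean log2 CPM of marker lists in each library, by layer and group. The meningeal score in L2-3 was 7.22 ± 0.361 in FOXP2 mice and 6.15 ± 0.778 in GFP mice, and the oligodendrocyte score in L5-6 was 6.50 ± 0.314 and 7.10 ± 0.766 (SD, n = 3 each).

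The FOXP2 effect in L5-6 was compared with that in L2-3 of the same mice. The potassium channel gene Kcnq3 had a difference of 0.91 ± 0.14 (adjusted p = 0.0084), and the glutamate receptor gene Grin2a one of 1.13 ± 0.19 (adjusted p = 0.00931). Foxp2 had -2.72 ± 0.35 (adjusted p = 0.0084) and Cntnap2 0.44 ± 0.10 (adjusted p = 0.0168, mean log2 ratio 0.0257 ± 0.183 against -0.422 ± 0.0575, n = 3 each). In all 2457 of 15952 genes passed, 1076 positive and 1381 negative, 672 of them at 2-fold or more. Among the genes of largest fold were Ostn (3.81 ± 0.77), Spx (3.12 ± 0.73), Rgs13 (3.02 ± 0.73), Glp2r (2.75 ± 0.53) and Grem1 (2.62 ± 0.59) on the high side, and S100a9 (-5.21 ± 1.56), Lbp (-4.16 ± 0.99), Lrrc23 (-4.00 ± 0.83), Prelp (-3.37 ± 0.67) and the retinoic acid binding protein gene Crabp1 (-3.33 ± 0.60) on the low side. huFOXP2 mouse 1 stood apart in photoreceptor genes chosen after their values were seen (Crx at 2.20 ± 0.498 CPM over its layers, at most 0.0190 CPM as the mean of any other mouse). Whether these genes had a part in the count was not tested. The count changed with the mouse left out. It was 1 without huFOXP2 mouse 1, 1001 without GFP mouse 3, 1129 without the moFoxp2 mouse, 1385 without GFP mouse 1, 1402 without huFOXP2 mouse 2 and 3414 without GFP mouse 2. It was 0 without the mouse block and 0 with the meningeal score of the library as a term, which was chosen after seeing the data. Without huFOXP2 mouse 1, without the block and with that score, in this order, adjusted p was 0.0625, 0.0725 and 0.0965 for Foxp2 (range 1.68e-51 to 0.0965), 0.108, 0.305 and 0.151 for Cntnap2 (range 0.00333 to 0.305), 0.0625, 0.125 and 0.0965 for Kcnq3 (range 9.64e-13 to 0.125) and 0.0668, 0.119 and 0.114 for Grin2a (range 3e-13 to 0.119). Cntnap2 was also lost without the moFoxp2 mouse (0.0528).

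In the same comparison 16 gene lists passed with camera at the preset correlation, and 0 at an estimated one. The medians below include GFP mouse 1, which stood apart in L2-3 and in L5-6, as given above. Of 17 contactin and neurexin family genes 17 were above 0, and 8 passed over all genes and 13 when adjusted over the list alone (median 0.44). GABA-A receptors (0.45, 7 of 12 over all genes, 7 when adjusted over the list alone), potassium and HCN channels (0.43, 10 higher of 18, and 13 higher and 1 lower when adjusted over the list alone), glutamate receptors (0.15, 7 of 19, 7), layer 2-3 markers (0.64, 7 of 11, and 7 higher and 1 lower) and layer 4 markers (0.82, 4 of 8, 6) also passed above 0. Below 0 passed the markers of meningeal fibroblasts (-1.57, 2 of 9 over all genes, 7 when adjusted over the list alone), endothelial cells and pericytes (-0.73, 6 of 10, 9), astrocytes (-0.81, 6 of 10, 7), oligodendrocytes (-0.84, 5 of 12, 8), microglia (-0.69, 4 of 11, 8), red blood cells (-1.16, 4 of 4, 4) and ependyma (-1.68, 2 of 5, 3). Cell cycle genes (-0.78, 5 of 9, 8), retinoic acid pathway genes (-0.85, 6 of 13, 8) and ribosomal protein genes (-0.35, 12 of 18, 15) were below 0 too. With an estimated correlation these 16 lists had adjusted p between 0.261 and 0.302, while with fry, which tests a list by itself, there passed these and the heat shock, interferon response and reported FOXP2 target lists (19 in all). Examples were Cntn6 (0.89 ± 0.13), Rorb (2.27 ± 0.49), Sox9 (-0.97 ± 0.21), Sox10 (-0.99 ± 0.23) and Hba-a1 (-1.48 ± 0.34). Lists that did not pass camera were Foxp partners (median 0.11), layer 5 (-0.22), layer 6 (-0.51), interneuron (-0.26), Cajal-Retzius (-0.71), striatal (-0.53), hippocampal (-0.58) and thalamic markers (-0.29), immediate early (-0.08), heat shock (0.06), interferon response (-0.68) and axon guidance genes (0.34), and mitochondrially encoded genes (-0.27). Reported FOXP2 targets did not pass either, with a median of 0.05 and a mean of -0.03.

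When the effect in L4 was compared with that in L5-6, Foxp2 alone of 15952 genes passed (2.71 ± 0.34, adjusted p = 0.0278), with a mean log2 ratio of L4 to L5-6 of -0.510 ± 0.437 in FOXP2 mice and -3.20 ± 0.199 in GFP mice (n = 3 each). The unadjusted count was 892 genes (798 by chance). The call was lost without GFP mouse 2 (adjusted p = 0.153), GFP mouse 3 (0.179), huFOXP2 mouse 1 (0.591) or huFOXP2 mouse 2 (0.462) and without the block (0.99996, range 5.96e-54 to 0.99996). In the fits that lost the call the difference was 2.58 to 2.84. Layer 5 markers had a median of -0.55, with Etv1 and Fezf2 lower when adjusted over the list alone (adjusted p = 0.000436, adjusted p = 0.322 with an estimated correlation). Striatal markers had a median of 0.72, with 1 of 9 higher when adjusted over the list alone (adjusted p = 0.000509, adjusted p = 0.409 with an estimated correlation). Between L4 and L2-3 edgeR called 0 genes, with 2831 at an unadjusted p under 0.05 (798 by chance), and DESeq2 called 527. Foxp2 differed there by -0.01 ± 0.37. All 12 GABA-A receptor genes were above 0 and 7 rose when adjusted over the list alone (median 0.39, adjusted p = 2.3e-07, adjusted p = 0.139 with an estimated correlation), the 1 list that passed with fry there (0.0128). Meningeal markers had a median of -1.27, with 7 of 9 lower when adjusted over the list alone (adjusted p = 4.96e-06, adjusted p = 0.294 with an estimated correlation). No list member passed over all genes in either comparison, and 0 lists passed with fry between L4 and L5-6.

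Human and mouse FOXP2 were then set against GFP and against each other. In huFOXP2 mice Ddah1, an enzyme gene that breaks down an inhibitor of nitric oxide synthesis, fell by 0.94 ± 0.12 in L4 (87.2 ± 5.56 against 166 ± 12.3 CPM, n = 2 and 3, adjusted p = 0.00762) and by 0.94 ± 0.12 in L5-6 (adjusted p = 0.00699). The neurofilament gene Nefm fell by 1.19 ± 0.16 in L2-3 (adjusted p = 0.0194), and Cap2, an actin regulator, rose by 0.87 ± 0.11 in L5-6 (adjusted p = 0.00706). Each of these calls was lost without huFOXP2 mouse 1, huFOXP2 mouse 2 or GFP mouse 2. In that order adjusted p was 0.392, 0.340 and 0.0863 for Ddah1 in L4 (range over alternatives 1.12e-10 to 0.392), 0.725, 0.172 and 0.0763 for Ddah1 in L5-6 (1.32e-11 to 0.744), 0.839, 0.101 and 0.1001 for Nefm (3.88e-10 to 0.839) and 0.719, 0.113 and 0.102 for Cap2 (3.58e-09 to 0.744). Without GFP mouse 3, Ddah1 in L4 (0.0693), Nefm (0.0960) and Cap2 (0.0661) were lost too, and in fits over the libraries of 1 layer all of these calls were lost (0.119 to 0.744). Leaving out huFOXP2 mouse 1 or 2 leaves 1 huFOXP2 library per layer. Differences were then -1.01 and -0.88 for Ddah1 in L4, -0.85 and -1.04 for Ddah1 in L5-6, -1.05 and -1.33 for Nefm and 0.77 and 0.96 for Cap2. These losses therefore do not show that 1 mouse carried the differences. Ddah1 was also lower in L2-3 (-0.70 ± 0.12, edgeR adjusted p = 0.0760), which did not pass. In L5-6, whose cells the labels call GFP-negative, Foxp2 had 58.8 ± 27.0 against 61.0 ± 7.98 CPM. A trait of these 2 outbred mice was not separated from an effect of huFOXP2 on Ddah1. Nefm was also higher in L4 than in L2-3 of GFP mice, as given below. Different tissue content of the L2-3 dissections was not separated from an effect on Nefm. Meningeal markers of L2-3 had a median of 1.08 in huFOXP2 mice, 8 of 9 higher when adjusted over the list alone (adjusted p = 3.03e-07, adjusted p = 0.353 with an estimated correlation). Part of this rested on GFP mouse 1, with a meningeal score of 5.27 there against 6.74 and 6.43 in the other GFP mice and 7.58 and 7.21 in the huFOXP2 mice. In the single moFoxp2 mouse, the DNA repair helicase gene Ercc2 had 6.26 CPM in L4 against 26.6 ± 1.98 CPM in GFP mice (-2.08 ± 0.22, adjusted p = 0.00173, range 1.63e-12 to 0.0460). The adjusted p-values of this mouse rest on the spread of the other groups and take the layers of a mouse as independent, so they do not support a change in moFoxp2 mice as a group. Ostn, below the 1 CPM of the rule for named genes and chosen after its values were seen, had a difference of 4.31 ± 0.56 in L5-6 (28 counts against 1 to 2, adjusted p = 0.0119). That call was lost without GFP mouse 1 (0.103), GFP mouse 2 (0.172) or GFP mouse 3 (0.0730) and in a fit over the libraries of the layer (0.637, range 3.05e-07 to 0.637). The pseudogene Gm13443, chosen likewise, was lower in all 3 layers of that mouse (-5.88 ± 0.81 in L4, a call lost without GFP mouse 1 (0.103) or GFP mouse 2 (0.178), range 4.95e-19 to 0.178). It was also lost in L2-3 without GFP mouse 2 (0.168, range 5.15e-21 to 0.168), and in L5-6 without GFP mouse 1 (0.101) or GFP mouse 2 (0.172) and in a fit over the libraries of the layer (0.637, range 8.15e-20 to 0.637). Of 6 Cajal-Retzius markers in L2-3 of the moFoxp2 mouse 3 passed above 0 when adjusted over the list alone (median 1.23, adjusted p = 4.61e-06, adjusted p = 0.112 with an estimated correlation), the 1 list that passed with fry against GFP, and no list member passed over all genes. Counts in L4, L2-3 and L5-6 were 4, 4 and 6 of 16970 genes for huFOXP2 and 5, 4 and 5 for moFoxp2. Foxp2 did not pass in any of these, with 2.89 ± 0.48, 2.99 ± 0.49 and -0.05 ± 0.45 for huFOXP2 and 2.39 ± 0.57, 2.23 ± 0.58 and 0.19 ± 0.56 for moFoxp2. The lone moFoxp2 library of each layer was assumed to vary like the other groups, and an effect of mouse Foxp2 was not separated from other features of that mouse.

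Between the 2 huFOXP2 mice and the 1 moFoxp2 mouse, Ercc2 differed by 1.74 ± 0.22 in L4 (adjusted p = 0.0352), and Gm13443 by 5.59 ± 0.76 and Ddah1 by -1.14 ± 0.15 in L2-3 (each adjusted p = 0.0372). The moFoxp2 mouse stood apart from all other mice over its layers in Ercc2 (9.54 ± 2.95 CPM against means of 19.3 to 26.2) and Gm13443 (0.227 ± 0.0498 CPM against 7.09 to 12.99), and the huFOXP2 mice in Ddah1 (108 and 110 CPM against 191 to 216). With 1 moFoxp2 mouse these tests did not separate the construct from the mouse. In L5-6 edgeR called 0 genes, with 291 at an unadjusted p under 0.05 and 3 by DESeq2. Ercc2 was lost without huFOXP2 mouse 1 (adjusted p = 0.272) or huFOXP2 mouse 2 (0.0991, range 5.83e-07 to 0.473), Ddah1 without either (0.692 and 0.430, range 1.73e-08 to 0.692) and Gm13443 without huFOXP2 mouse 1 (0.124, range 6.73e-19 to 0.125). In fits over the libraries of 1 layer all 3 were lost (0.473, 0.235 and 0.125). Foxp2 differed by 0.50 ± 0.62, 0.75 ± 0.64 and -0.24 ± 0.59 in L4, L2-3 and L5-6 (adjusted p = 1 each). Leaving out huFOXP2 mouse 1 or 2 leaves 1 library on each side. Ercc2 then differed by 1.65 and 1.82 in L4, and Ddah1 by -1.14 and -1.15 in L2-3. Simulated 2-fold changes in L2-3 were recovered at 16%.

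In GFP mice, L5-6 and L2-3 differed in layer, myelin and meningeal markers. Against L2-3, L5-6 had higher levels of the layer 6 genes Tle4 (2.49 ± 0.10) and Foxp2 (3.81 ± 0.29, 61.0 ± 7.98 against 4.54 ± 2.50 CPM, n = 3 each, adjusted p = 7.94e-05), the layer 5 gene Fezf2 (2.96 ± 0.20) and the myelin gene Mobp (7.68 ± 0.26). L2-3 had higher levels of the upper-layer transcription factor gene Pou3f2 (-1.77 ± 0.09) and of meningeal Dcn (-6.32 ± 0.29) and Aldh1a2 (-6.51 ± 0.30). Of 15698 genes, 3566 passed, 1889 higher and 1677 lower in L5-6. Layer 6 markers (median 2.51, 11 of 13 higher and 1 lower) and oligodendrocyte markers (1.99, 12 of 12 higher) were higher, and meningeal markers (-4.72, 9 of 9 lower) and Cajal-Retzius markers (-2.70, 4 of 5 lower) lower. Adjusted over the list alone the counts were the same except for 5 of 5 Cajal-Retzius markers, and adjusted p was 0.19, 0.252, 0.19 and 0.19 with an estimated correlation. The test with an estimated correlation thus missed the oligodendrocyte and meningeal lists, whose members all passed over all genes. Cntnap2 was lower in L5-6 (-0.42 ± 0.07, adjusted p = 0.0033), a call lost without GFP mouse 3 (0.0776), without the mouse block (0.254) and with all 6 mice (0.0762, range 0.000111 to 0.254). The counts without GFP mouse 3 were 1124 here, 19 for L4 against L2-3 and 670 for L5-6 against L4.

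L4 and L2-3 of GFP mice differed in 952 genes, 262 higher and 690 lower in L4. The neurofilament genes Nefm (1.68 ± 0.11, adjusted p = 0.000419) and Nefl (1.49 ± 0.11) were higher in L4, and Gfap was lower (-2.60 ± 0.24), a call lost without GFP mouse 3 (0.0756, range 6.29e-31 to 0.0756). The rule names list members by smallest p, or by largest fold among called genes. That named markers passed therefore does not describe the other members of their lists. The named markers of layer 5 and of layer 6 and subplate neurons were past the threshold and higher in L4. These were Fezf2 (2.53 ± 0.20, 33.2 ± 11.4 against 5.97 ± 3.43 CPM), Etv1 (1.05 ± 0.09), Nxph3 (2.00 ± 0.35), Rprm (1.27 ± 0.15) and Hs3st4 (1.19 ± 0.17). Layer 4 markers had a median of 0.27 and did not pass (adjusted p = 0.058). Of them Whrn was higher in L4 (0.89 ± 0.22, adjusted p = 0.0489), a call lost without GFP mouse 2 (0.310), GFP mouse 3 (0.283) or the mouse block (0.150, range 4.88e-06 to 0.310), and Scnn1a had a difference of 0.89 ± 0.26 (adjusted p = 0.0873). The layer 2-3 markers did not pass either (adjusted p = 0.514), with Pou3f2 lower in L4 (-0.39 ± 0.08) and Rasgrf2 at 0.35 ± 0.15 (adjusted p = 0.233). Meningeal markers were lower in L4 (-3.89, 9 of 9, also when adjusted over the list alone, adjusted p = 0.0931 with an estimated correlation). The count was 3711 without GFP mouse 1 and 74 without GFP mouse 2. L5-6 and L4 differed in 3563 genes, 1999 higher and 1564 lower in L5-6. Cux2 (-2.16 ± 0.24) and the vesicular glutamate transporter gene Slc17a6 (-2.13 ± 0.18) were lower in L5-6, and the subplate genes Cplx3 (4.58 ± 0.23) and Ctgf (4.43 ± 0.35) higher. Layer 4 markers had a median of -1.02 with 6 of 8 lower, and microglia markers one of 0.82 with 10 of 11 higher. Adjusted over the list alone the counts were the same, and adjusted p was 0.312 and 0.115 with an estimated correlation. With fry 15 lists passed between L5-6 and L2-3, 16 between L4 and L2-3 and 22 between L5-6 and L4.

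Summed over the layers of each mouse, 3 of 17462 genes passed, 2 higher and 1 lower, all of them the pseudogenes Gm6166 (7.22 ± 0.13), Gm11942 (6.56 ± 0.47) and Rpsa-ps10 (-5.84 ± 0.33). The call of Gm11942 was lost without GFP mouse 1 (adjusted p = 0.0789) or GFP mouse 2 (0.0549, range 9.23e-57 to 0.0789). Foxp2 had a difference of 0.84 ± 0.29 (46.1 against 25.7 CPM, adjusted p = 1) and Cntnap2 one of 0.20 ± 0.13. Meningeal markers had a median of 1.07 with 9 of 9 above 0 (adjusted p = 0.464 with an estimated correlation), and oligodendrocyte markers one of -0.43 with 12 of 12 below 0 (0.743). These medians include GFP mouse 1, which stood apart from the other GFP mice. Its meningeal score in L2-3 was 5.27 against 6.74 and 6.43, and its oligodendrocyte score in L5-6 was 7.92 against 6.40 and 6.98. Ependyma markers had a median of -1.40, and 4 of 7 fell when adjusted over the list alone (adjusted p = 0.464 with an estimated correlation). No list member passed over all genes, 0 lists passed with fry, and 715 genes had an unadjusted p under 0.05 (873 by chance).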

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

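The tests of the 3 patterns weighed here were chosen after the results were seen, and the counts over other splits of the mice were planned.

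Differences of the FOXP2 effect between layers were tested themselves. In L4 against L5-6 the number of genes past the threshold was 1, namely Foxp2 (2.71), a call lost without GFP mouse 2, GFP mouse 3, huFOXP2 mouse 1, huFOXP2 mouse 2 or the mouse block. In L5-6 against L2-3 it was 2457, with Foxp2 at -2.72, Cntnap2 at 0.44, Crabp1 at -3.33, Glp2r at 2.75, Prelp at -3.37, Ostn at 3.81, Lrrc23 at -4.00, Grem1 at 2.62, Spx at 3.12, Lbp at -4.16, Rgs13 at 3.02 and S100a9 at -5.21 (log2). That count was 1 without huFOXP2 mouse 1, and 0 without the mouse block or with the meningeal score as a term. Which part of it belongs to FOXP2 was not settled. Libraries of huFOXP2 mouse 1 also held photoreceptor transcripts (Crx at 2.20 CPM over its layers, against at most 0.0190), whose part in the count was not tested. Without that mouse Foxp2 differed by -2.67 and Cntnap2 by 0.34. The fit without the block ignores the pairing of layers within a mouse, and differences there hardly moved (Foxp2 -2.74, Cntnap2 0.43). Between the huFOXP2 mice and the lone moFoxp2 mouse 1 gene passed in L4 (Ercc2, 1.74) and 2 in L2-3 (Ddah1, -1.14, and Gm13443, 5.59). Ercc2 and Gm13443 were low in all 3 layers of the moFoxp2 mouse, and with 1 such mouse the construct is not separated from the mouse.

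Gm6166 and Gm11942 were high, and Rpsa-ps10 low, in every library of the 3 FOXP2 mice. Regulation by FOXP2 inside the electroporated cells would leave Rpsa-ps10 in the other cells, yet its level in L5-6 was 1.42% of that of GFP mice, which argues against it. Reads from the plasmid would add to a gene, so the low Rpsa-ps10, at most 3.72% of the lowest GFP library in any layer, argues against them as its source. As the source of the high Gm6166 and Gm11942 they stay undecided. They would follow Foxp2 across layers, and the ratio to L4 was 0.868 ± 0.00154 for Gm6166 against -0.0645 ± 0.632 for the excess of Foxp2 over GFP mice in L5-6, and 1.01 ± 0.0556 against 0.667 ± 0.121 in L2-3 (SD, n = 3). The ratio of Gm6166 was the higher one in all 3 mice in both layers. In L5-6 the excess of Foxp2 lay within the spread of mice (62.4 ± 20.1 against 61.0 ± 7.98 CPM). It was negative in huFOXP2 mouse 1 (ratio -0.795), so that layer cannot decide on the plasmid. The order in L2-3 goes against the plasmid, but an exact sign-flip test over 3 mice gives no p below 0.25 (p = 0.25 in each layer). Sequence variants among outbred mice at genes with near-identical copies stay open as a candidate explanation, since 17 of 30 other divisions of the mice also held a gene with a 4-fold gap, and 13 of those 29 genes were pseudogenes, against 1.52% of 14330 genes examined. The parent gene Rpsa had 731, 548 and 617 CPM over the layers of GFP mice and 635, 639 and 563 CPM in FOXP2 mice, so no rise of Rpsa matched the reads missing from Rpsa-ps10, and where these reads went is not known. Why mice carrying such variants would then part into the FOXP2 and GFP groups is not known, and these libraries do not decide it.

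Medians of non-neuronal markers stood higher in L2-3 and lower in L5-6 of FOXP2 mice. In either layer 0 lists passed with an estimated correlation and 0 with fry. In L5-6 much of the lower level rested on GFP mouse 1, without which the medians went from -0.72 to -0.23 for oligodendrocyte and from -0.38 to 0.04 for astrocyte markers. The endothelial median there also lost most of its size without that mouse, as given above. That mouse also had the lowest meningeal score in L2-3 (5.27 against 6.43 to 7.58), where the medians without it were 0.67 for meningeal, 0.77 for microglia, 0.56 for endothelial and 0.55 for astrocyte markers. Different tissue content of the dissections stays open and undecided: 98.4% (60 of 61) of the fixed non-neuronal markers had an effect below 0 in L5-6 against L2-3, which restates the pattern and was no test of its source. Meningeal tissue as the whole source stays undecided: with the meningeal score of each library as a term, chosen after seeing the data, the median size of 2455 called genes went from 0.741 to 0.609, the median SE from 0.185 to 0.232 and the number of calls to 0, while all 2455 kept their sign. The calls ended with both a smaller fold and a larger error. A biological effect of FOXP2 on these layers stays open, as its own part was not tested.

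Foxp2 had 31.03 CPM in L2-3 of FOXP2 mice and 4.54 CPM in GFP mice (adjusted p = 0.0829), where the labels call the cells GFP-negative. Tissue of L4 or of L5-6 in the L2-3 dissections stays open and undecided as the source. The shares needed by Foxp2 were 0.513 to 0.770 of L4 tissue or 0.233 to 0.629 of L5-6 tissue. Against the level of a mixture of this share with L2-3 of GFP mice, medians of layer 4 markers in the moFoxp2 mouse, huFOXP2 mouse 1 and huFOXP2 mouse 2 were -0.92 ± 0.19, -0.59 ± 0.19 and -0.89 ± 0.24 (log2 ± SE over markers, 7 of 7 below in each), and of layer 6 and subplate markers -0.49 ± 0.19, -1.11 ± 0.36 and -2.44 ± 0.41 (11, 10 and 12 of 12 below). The layer 6 and subplate values go against L5-6 tissue but assume the L2-3 profile of GFP mice. Layer 4 markers could not decide on L4 tissue. The needed share predicted their median only 0.08 to 0.38 (log2) above that profile, and it lay at -0.72 to -0.52 against the profile itself. Markers were therefore also set against the level that the share would bring by itself. Of 7 layer 4 markers 5, 2 and 7 lay below that level in the same order, with a highest median of 0.135 (log2). Of 12 layer 6 and subplate markers 5, 8 and 12 lay below it, with a highest median of 0.206 in the moFoxp2 mouse, where the needed share was 0.233, and a lowest of -2.33 in huFOXP2 mouse 2. The introduced cDNA read out in cells of L2-3 stays open and undecided, because gene counts do not separate it from the endogenous gene. The lowest FOXP2 library was 3.07 times the highest GFP library (20.3 against 6.62 CPM), which restates the pattern.

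With 3 mice against 3 there are 10 splits, so the share of splits with a count as large is never under 0.1. In L4 the real count was 4 and the highest other 3 (1 split as large, the real one), in L2-3 11 and 2 (1), in L5-6 3 and 1 (1) and summed per mouse 3 and 4 (2). For the effect in L4 against L2-3 they were 0 and 1 (10), in L4 against L5-6 1 and 0 (1) and in L5-6 against L2-3 2457 and 0 (1). Layers of GFP mice gave 3566 and 1, 952 and 0, and 3563 and 0 (1 each), and 4 of the 10 splits part the layers of all 3 mice.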

How the results depend on the processing

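The meningeal score was added as an alternative after seeing the data, and the other alternatives were planned. Counts below are genes past the threshold, for L4, L2-3 and L5-6 in this order where 3 are given, and the cause of a change was not tested unless stated. FOXP2 against GFP gave 4, 11 and 3 by edgeR, 32, 755 and 56 by DESeq2 and 189, 865 and 323 without a filter, where more genes are tested. huFOXP2 against GFP gave 4, 4 and 6, with 22, 218 and 27 by DESeq2 and 150, 901 and 534 without a filter. moFoxp2 against GFP gave 5, 4 and 5, with 8, 31 and 12 by DESeq2 and 94, 430 and 122 without a filter. huFOXP2 against moFoxp2 gave 1, 2 and 0, with 5, 11 and 3 by DESeq2 and 80, 230 and 54 without a filter. Summed per mouse, 3 became 62 by DESeq2, 58 without a filter and 15 with duplicateCorrelation of limma. The effect in L4 against L2-3 (0 by edgeR, 2831 at an unadjusted p under 0.05) became 527 by DESeq2, 1326 without a filter and 1 with RLE size factors, and that in L4 against L5-6 (1) became 11 by DESeq2 and 255 without a filter. With RLE size factors L2-3 gave 4 (3 higher, 1 lower), with sex as a term 3, with the meningeal score 4 (2 of them among the 11) and in a fit over 18 libraries 43, where L5-6 gave 17. With the meningeal score the effect in L5-6 against L2-3 went from 2457 to 0 calls. Fits over the libraries of 1 layer gave 3 for huFOXP2 and 1 for moFoxp2 against GFP in L5-6, and 0 and 0 between them in L4 and L2-3. L4 against L2-3 of GFP mice went from 952 to 2086 without a filter. With all 6 mice the layers gave 5795 (L5-6 against L2-3), 5586 (L4 against L2-3) and 5364 (L5-6 against L4).

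Without the mouse block, counts were 0 and 0 for the effects in L4 against L5-6 and L5-6 against L2-3, and 1444, 376 and 918 for L5-6 against L2-3, L4 against L2-3 and L5-6 against L4 in GFP mice. Such fits ignore the pairing of layers within a mouse. GFP and huFOXP2 mice share only a number: differences between numbers 1 and 2 correlated at 0.117 in L4, -0.00586 in L2-3 and 0.118 in L5-6. With that number as a replicate block and moFoxp2 left out, FOXP2 against GFP gave 69, 9 and 45, and 8 summed per mouse. The same libraries without the block gave 5, 7 and 2, and 4 summed. huFOXP2 against GFP gave 69, 9 and 45 with the block. For moFoxp2 no fit with the number as a block was made.

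Leaving out each mouse in turn gave ranges of 3 to 6, 3 to 195 and 2 to 4 for FOXP2 against GFP, and 2 to 7 summed per mouse. They were 0 to 14 for the effect in L4 against L2-3, 0 to 2 in L4 against L5-6 and 1 to 3414 in L5-6 against L2-3. Ranges were 3 to 15, 3 to 549 and 3 to 12 for huFOXP2, 2 to 7, 1 to 606 and 1 to 5 for moFoxp2 and 0 to 0, 0 to 3 and 0 to 3 between them, and the highest values in L2-3 came without GFP mouse 1 (195, 549 and 606). Layers of GFP mice gave 1124 to 5262, 19 to 3711 and 670 to 4332. Of list tests, 216 passed with the preset correlation and 0 with an estimated one. The estimated correlation passed 0 of 30 lists also between L5-6 and L2-3 of GFP mice, where 3566 genes were called and fry passed 15 lists. Failing that test therefore does not show a list to be unchanged. With fry 0 lists passed for FOXP2 against GFP in each layer and summed, 1 for the effect in L4 against L2-3, 0 in L4 against L5-6 and 19 in L5-6 against L2-3. Of 7113 alternatives for named genes, called or not, 5936 kept their direction and side of the threshold, 595 lost the call and 552 gained it. The other 30 changed direction, all for genes not called in the main fit, and no called gene changed direction. Depth, from 10111149 counts in a library, limits what can be seen for genes of low level.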

Other observations

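The photoreceptor list and the genes of single mice were chosen after their values were seen, and no test was made on them.

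In huFOXP2 mouse 1, most genes of retinal photoreceptors stood above all other mice. The photoreceptor transcription factor gene Crx had 2.20 ± 0.498 CPM over its layers (SD, n = 3 layers of 1 mouse), against at most 0.0190 CPM as the mean of any other mouse, and the arrestin gene Sag 7.51 ± 2.69 CPM against at most 1.02. Of 14 photoreceptor genes, 11 were above every other library in all layers of that mouse, and Gnat1, Gnat2 and Arr3 were not. The serine protease gene Prss56 had 16.6 ± 5.37 CPM there, against at most 0.818.

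Single mice also differed in other genes. Pop4, a subunit gene of ribonuclease P, had 26.1 ± 2.45 CPM in the moFoxp2 mouse (SD over 3 layers) and 7.14 to 10.99 CPM in the others. Vcp-rs had 35.3 CPM in the moFoxp2 mouse and 60.3 to 74.5 CPM in the others. Ddah1 had 108 and 110 CPM in the huFOXP2 mice and 191 to 216 CPM in the others. Layer lists not described above also differed in GFP mice: interferon response genes had a median of -0.85 in L5-6 against L2-3 and -1.03 in L4 against L2-3, and cell cycle genes one of 0.90 in L5-6 against L4, with 9 of 9 higher. Adjusted p with an estimated correlation was 0.395, 0.105 and 0.144.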
